A study of Mus musculus with 10 samples.

How the data were processed

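Gene expression was measured in skin wounds of genetically diabetic db/db mice, which lack a working leptin receptor and become obese and hyperglycaemic. Per the labels' protocols, male mice aged 11 weeks received 2 full-thickness dorsal wounds made with a 4 mm punch. Each wound was injected at 4 points of its edge with 0.5 nmol of miR-132 mimic or control mimic in 100 µl. A mimic is a synthetic RNA that acts like the mature microRNA, and a microRNA lowers the messenger RNAs whose sites it pairs with. Wound-edge biopsies were taken 6 days after injury, and 150 ng of total RNA per sample went to Affymetrix mouse Clariom D arrays, which measure transcript clusters with many short probes each. The labels give 5 mice per group, so the 10 arrays stand for 10 animals. Whether both wounds of a mouse were combined in 1 sample is not given in the sources used here.

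Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.4 with RMA, which corrects background, normalizes arrays to each other and summarises the probes of a cluster. The deposited values are taken here as log2 signal, a scale the labels do not state. The basis is their range and their shared upper limit of 19.93, which is the log2 of 1000000. A value at that limit is only a lower bound, and 216 of the tested genes reached it on at least 1 array, 107 of them on all 10. The values carry 2 decimals. The genome build behind the clusters is not given in the sources used here, so no coordinates are printed. All 10 value columns matched a sample by its label, 0 columns were left unmatched, and 0 pairs of arrays held identical values.

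The table held 72688 features, of which 65770 were transcript clusters, 6732 were control or spike-in features and 186 were clusters with no mapped position. Gene symbols came from the platform annotation. It paired 31085 features with 1 gene and 1665 with several, and 39938 are unnamed here. Symbols were updated through gene identifiers for 1435 features, with the reference gene table of assembly GRCm38.p6 used for names only. Features with several genes were not named or tested. For the 356 genes with more than 1 feature, the one with the highest mean over all 10 arrays was kept. Genes were tested if their mean over all arrays lay above 4.17, the median of such means over all features, which left 17563 of 30633 genes.

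The comparison of miR-132 with control mimic used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on the deposited log2 values of all 10 arrays without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are miR-132 minus control on the log2 scale, for genes with the moderated standard error (SE). For gene lists, limma's fry tested whether the members moved on balance in 1 direction, adjusted over 28 lists. The SE of a list mean is not moderated. It comes from the spread of the list means per array within each group, and fry's p does not rest on it. Members at an adjusted p under 0.05 were counted over all genes tested and adjusted over the list alone. The number of arrays limits the precision of every value. On simulated arrays with the spread of this comparison, independent noise and 17563 genes, the procedure called 74% of genes changed 2-fold and 97% of genes changed 4-fold. It called 7 unchanged genes in that simulation and 0 genes when no change was simulated. The changed genes were drawn at random, each with its own spread. The median SD over all genes was 0.17 in controls and 0.23 with miR-132. These shares do not carry over to genes with a wider spread, such as Krt17 (SD of 1.40 with miR-132) and Hbegf (0.92). With the same noise, 4 of 4 lists shifted by 0.5 were called. The simulated members varied independently, whereas members of a real list can vary together. The correlation that limma's camera estimated was 0.45 for wound-activated keratinocyte genes and 0.32 for NF-kB response genes. The list recovery does not carry over to such lists.

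Before the data were examined, 30 gene lists were fixed, 15 for functions and 15 for cell types that wound-edge skin can hold, with 503 distinct members. Of these, 459 matched a feature with 1 gene, 3 of them by another symbol. A further 18 shared their features with another gene, and 26 had no feature named here. Lists needed 4 measured members, which the B and plasma cell list and the red blood cell list lacked. The rule for named genes was fixed at the same time. It takes the 12 raised and 12 lowered genes with the largest change among those past the threshold with non-overlapping groups. Where fewer pass, it fills up with the smallest unadjusted p in that direction, leaving out predicted genes and small RNAs. It adds the features of Mir132 and Mir212, the 4 members of each list with the smallest p, and Hbegf. Since 0 genes passed, every gene named by this rule fell short of the threshold.

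The alternatives fixed beforehand changed 1 choice at a time. They were no level filter, a filter at the 75th percentile of feature means, the mean of a gene's features, every cluster tested on its own, and a minimum change of 1.5-fold. Further ones were median centring, a further quantile normalization, no intensity trend, robust variances, array weights, the replicate number as a block, and leaving out each array. Lists were also tested with camera (preset correlation of 0.01, or estimated), with fry for either direction, and with an exact permutation test of the list mean per array over 252 assignments, whose smallest two-sided p is 0.0079. Added after the data were seen were leaving out miR-132 replicates 2 and 5, the mean of 4 hybridisation controls as a covariate, and quantile normalization without miR-132 replicate 3.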

Results

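The data were 10 arrays of wound-edge skin from diabetic db/db mice, taken 6 days after injury. Wounds of 5 mice had received a miR-132 mimic and wounds of 5 other mice a control mimic. The design asks which transcripts of a diabetic wound differ when miR-132 is supplied locally. The signal of an array spanned 4.81 to 5.03 on the log2 scale between its 10th and 90th percentile in controls. This span was 4.92, 4.41, 4.88, 4.89 and 4.63 on miR-132 replicates 1 to 5, so replicates 2 and 5 had the narrowest ranges. The spike-in controls added at hybridisation averaged 10.80 ± 0.19 (SD, n = 5) with miR-132 and 10.54 ± 0.07 (SD, n = 5) in controls, an exact permutation p of 0.0317 and an adjusted p of 0.254 over 32 comparisons of control features. On miR-132 replicates 3 to 5 they stood at 10.9 to 10.98, above every control array (10.43 to 10.61). As a covariate they are therefore partly confounded with treatment. Values with this covariate rest in part on extrapolation and cannot tell hybridisation from treatment.

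Wounds given miR-132 had lower average levels of keratinocyte wound-response genes, glycolysis genes, NF-kB response genes and immediate early genes than wounds given control mimic, but over all 10 arrays no gene passed limma's adjusted threshold and no list passed fry's. Krt17, a keratin that keratinocytes switch on in wounds, averaged 2.73-fold lower, with a log2 difference of -1.45 ± 0.58 (SE, n = 5 per group). Il1rn, which encodes the interleukin-1 receptor antagonist, averaged 3.07-fold lower (-1.62 ± 0.32). Nfkbia, an inhibitor of NF-kB that is itself induced by it, averaged 2.27-fold lower (-1.18 ± 0.38), and Hk2, a hexokinase of glycolysis, 2.24-fold lower (-1.17 ± 0.37). Among markers of other cell types, neutrophil markers averaged -0.45 (14 of 15 lower, -0.24 without control replicate 4), basal keratinocyte markers -0.28 (10 of 10 lower, -0.13 without control replicate 2) and adipocyte markers 0.47 (14 of 14 higher, 0.07 without miR-132 replicate 1), sebaceous gland (-0.41) and muscle markers (-0.39) were lower but turned higher with the hybridisation controls as a covariate, and markers of macrophages, fibroblasts and endothelium averaged within 0.10 of the control mean.

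Of 17563 genes tested with limma, 0 passed an adjusted p of 0.05, and the lowest adjusted p was 0.597. At an unadjusted p under 0.05 there were 1419 genes, 987 lower and 432 higher with miR-132, where chance alone gives 878. Without miR-132 replicate 3, 55 genes passed adjustment, all of them lower, and 2473 genes lay under the unadjusted threshold. With quantile normalization as well, 0 genes passed adjustment. Without control replicate 5 the unadjusted count was 944. The share of lower genes, 69.6% on the deposited values, was 48.6% after a further quantile normalization, 47.8% after centring each array on its median and 39.5% without miR-132 replicates 2 and 5 (401 lower, 614 higher). The groups did not overlap for 163 genes, 0.928% of those tested against 0.794% by chance, with 114 lower and 49 higher. Among genes at an unadjusted p under 0.05, 54 averaged at least 2-fold lower and 0 at least 2-fold higher. These counts were 36 and 2 after quantile normalization, 15 and 4 without miR-132 replicates 2 and 5, and 222 and 32 with the hybridisation controls as a covariate.

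The lowered genes with the smallest p did not pass the threshold (adjusted p of 0.597 for each) and were below the control mean on all 5 miR-132 arrays. Il1rn (cluster TC0200000382.mm.1) measured 12.10 ± 0.38 (SD, n = 5) in control wounds and 10.49 ± 0.64 (SD, n = 5) in miR-132 wounds, with no overlap. Tuba4a, an alpha-tubulin, measured 13.37 ± 0.38 and 11.75 ± 0.75 (SD, n = 5 each), a log2 difference of -1.62 ± 0.35. Its miR-132 replicate 3 lay within the control range. Sqstm1, an autophagy receptor, had a difference of -0.64 ± 0.12 (SE), and Ikbkb, a kinase that activates NF-kB, one of -0.29 ± 0.06 (SE). Genes of the cytoskeleton were Myo10, a myosin of filopodia, at -0.57 and Camsap1, which binds microtubule ends, at -0.47. The others were Zswim4 at -0.86, the phosphatase gene Ptpre at -0.70, Tmem51 at -0.63, Gtf2f1, a part of a general transcription factor, at -0.51, the splicing kinase gene Clk3 at -0.50, and Lrrc8b, a channel subunit, at -0.39. Without miR-132 replicate 3, Zswim4 (-1.03), Tuba4a (-1.94), Camsap1 (-0.55) and Tmem51 (-0.68) were among the 55 genes that passed. With quantile normalization as well they did not pass (limma's adjusted p of 0.0610 to 0.0863). Their differences were then -0.93, -1.70, -0.44 and -0.72.

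The raised genes with the smallest p were mostly dim and differed little, and they did not pass either (adjusted p of 0.597 for each). All 5 miR-132 arrays lay above the control mean for each of them. Ly96, which encodes the partner of toll-like receptor 4 in sensing bacterial lipopolysaccharide, measured 7.47 ± 0.41 (SD, n = 5) in controls and 8.25 ± 0.23 (SD, n = 5) with miR-132, 1.72-fold higher on average. Its groups overlapped through control replicate 5. The remaining differences were 0.39 for Tex13d, 0.35 for Rnf186, 0.32 for Coprs, 0.30 for Lpar2, a receptor of lysophosphatidic acid, 0.27 for Thnsl1 and for Alms1-ps2, 0.26 for Upk2, 0.25 for Cep83os and for Iqank1, 0.24 for the collagen gene Col28a1 and 0.22 for Znhit3. The median level of all raised genes at an unadjusted p under 0.05 was 4.75, against 7.02 for the lowered ones.

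**Figure D1:**
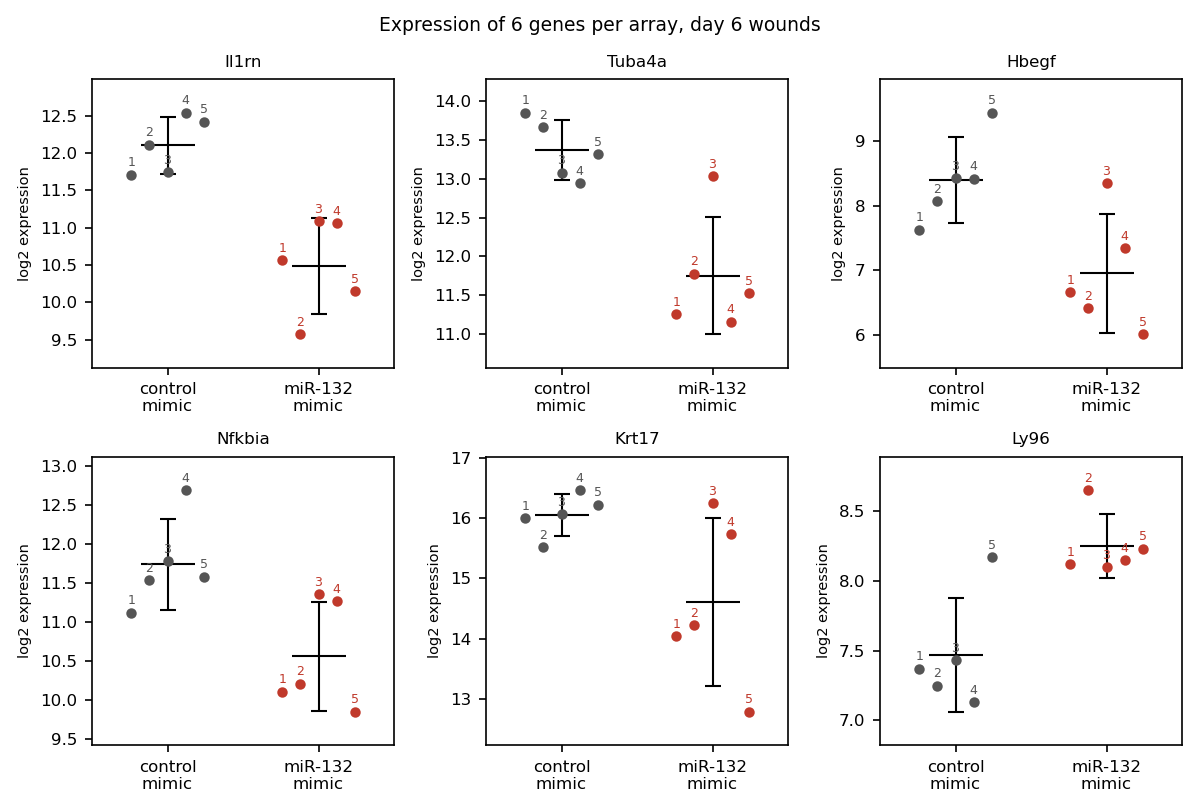
Log2 expression of 6 genes on each array (points, numbered by replicate) in control and miR-132 wounds, with the mean (horizontal line) and SD (bars). Il1rn does not overlap between groups, and Ly96 is higher with miR-132 on average. The control range holds miR-132 replicate 3 for Tuba4a, Hbegf, Nfkbia and Krt17, and miR-132 replicate 4 for Nfkbia and Krt17.

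The supplied microRNA itself was not visible on its precursor's feature. The Mir132 feature measured 3.21 ± 0.25 in controls and 3.38 ± 0.41 with miR-132 (SD, n = 5 each, limma's unadjusted p of 0.418), and the neighbouring Mir212 feature 3.12 ± 0.19 and 3.08 ± 0.17. Both lay below the level filter, and such features are designed on the gene's own transcript. Of 18 measured genes reported elsewhere as miR-132 targets, 11 averaged lower and 7 higher, and 6 of the lower ones had an unadjusted p under 0.05. Hbegf, an epidermal growth factor receptor ligand that drives keratinocyte migration, measured 8.40 ± 0.67 in controls and 6.95 ± 0.92 with miR-132 (SD, n = 5 each), 2.72-fold lower on average. Mmp9, a gelatinase, differed by -1.34, Cdkn1a, the cell cycle inhibitor p21, by -0.94, Btg2, an antiproliferative gene, by -0.61, Arhgap32 by -0.46 and Foxo3, a forkhead transcription factor, by -0.22. The list averaged -0.28 ± 0.09 (SE), with a median of -0.125. Hbegf and Btg2 lay below the control mean on 5 of 5 miR-132 arrays, Cdkn1a and Foxo3 on 4 of 5. The list did not pass fry (p of 0.109, adjusted p of 0.486), and its exact permutation p was 0.0238 (adjusted p of 0.413). Of its members, 0 passed adjusted over the list alone.

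Keratinocyte genes of the wound response averaged lower with miR-132, with a wide spread between arrays. Of 17 measured wound-activated keratinocyte genes, 16 averaged lower, and Krt16 stood at the signal limit on every array. Besides Krt17, the cornified envelope genes Sprr1b (-1.41) and Sprr1a (-1.02), the antimicrobial peptide gene Defb14 (-1.20), the connexin gene Gjb2 (-0.68) and Hbegf had an unadjusted p under 0.05. The list averaged -1.26 ± 0.62 (SE), with fry's p at 0.0447 and an adjusted p of 0.321. Its arrays ranged from 10.74 to 14.09 with miR-132 and from 12.97 to 13.97 in controls, and miR-132 replicate 3 was the highest of all 10. Without that array the difference was -1.72 and passed (adjusted p of 0.0217, and 0.0309 with quantile normalization as well), and without miR-132 replicates 2 and 5 it was -0.46. All 10 measured basal keratinocyte markers averaged lower, with a list mean of -0.28 ± 0.21 (SE, p of 0.0573, adjusted p of 0.321), with Trp63, the master regulator of stratified epithelium, at -0.68 and the integrin genes Itga3 at -0.42 and Itgb4 at -0.34. Differentiated keratinocyte markers averaged -0.29 ± 0.48 (adjusted p of 0.729), 11 lower and 8 higher of 20. Among them were the crosslinking enzymes Tgm1 (-1.87 ± 0.60, SE) and Tgm3 (-1.90 ± 0.66, SE), the first below the control mean on 4 and the second on 5 of 5 arrays, Cdsn at -0.78 and Sbsn at -0.65. When single arrays were left out, basal markers ranged from -0.37 (without control replicate 4) to -0.13 (without control replicate 2) and differentiated ones from -0.56 (without miR-132 replicate 1) to -0.08 (without control replicate 2). The signal limit was reached by 2 basal, 2 differentiated and 1 wound-activated gene on at least 1 array.

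Of the lists of inflammatory genes, NF-kB response and immediate early genes averaged lower, interferon response genes averaged higher and chemokines split, none of them past adjustment. Of 23 NF-kB response genes, 22 averaged lower and 8 of these had an unadjusted p under 0.05, among them Tnfaip3 (-0.91 ± 0.26), a brake on NF-kB, the cytokine gene Tnf (-0.78 ± 0.24), Bcl3 (-0.40 ± 0.12) and Nfkbia. The list averaged -0.41 ± 0.20 (SE, fry's p of 0.0532, adjusted p of 0.321), and 0 members passed adjusted over the list alone. Immediate early genes, induced within minutes of a stimulus and mostly transcription factors, averaged lower for 15 of 16 members, with a list mean of -0.38 ± 0.16 (p of 0.0432, adjusted p of 0.321). Egr3 (-0.63 ± 0.16, measured on a cluster with no mapped position) and Klf4 (-0.83 ± 0.24) passed adjusted over the list alone (0.0475 for the lowest) and not over all genes, with Ier3 at -1.05 and Egr1 at -0.34. Toll-like and NOD-like receptor genes averaged -0.13 ± 0.11 (adjusted p of 0.729), 14 of 23 lower, with Irak3 at -0.51, Nod2 at -0.42, Irak2 at -0.37 and Ticam1 at -0.13. Inflammatory chemokines split, with 8 lower and 9 higher of 17. The chemokine mean was -0.05, the median 0.09 and the direction of the test upward (adjusted p of 0.975), and the mean turned to 0.03 after quantile normalization and was -0.45 with the hybridisation controls as a covariate. Cxcl16 (-0.61) and Ccl3 (-1.09) lay lower on average, Ccl8 (0.72) and Ccl12 (0.64) higher. Single arrays weigh on Ccl8, at 17.04 on miR-132 replicate 4 (other miR-132 arrays 15.35 to 15.54), and on Ccl3, at 11.73 on control replicate 2 (other controls 7.72 to 10.33). Interferon response genes averaged higher for 19 of 21 members, by 0.13 ± 0.18 (adjusted p of 0.729), with Usp18 at 0.39, Zbp1 at 0.28, Irf7 at 0.24 and Bst2 at 0.20. Genes of alternative macrophage activation averaged 0.19 ± 0.24 (adjusted p of 0.729), 10 of 13 higher, with Retnla at 0.67, Igf1 at 0.30, Ccl24 at 0.24 and Tgfb1 at -0.23. With the hybridisation controls as a covariate that list turned to -0.11. When single arrays were left out, interferon genes ranged from -0.01 (without miR-132 replicate 1) to 0.22 (without control replicate 1), chemokines from -0.20 (without miR-132 replicate 4) to 0.07 (without miR-132 replicate 2), alternative activation from 0.05 (without miR-132 replicate 4) to 0.33 (without control replicate 5) and toll-like and NOD-like receptor genes from -0.19 (without control replicate 3) to -0.05 (without control replicate 4).

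Neutrophil markers averaged -0.45 ± 0.37 (SE, adjusted p of 0.612), with 14 of 15 lower, beside the lower NF-kB genes. Clec4e stood at -1.03, the receptor gene Csf3r at -0.92 and Hdc at -0.87, all below the control mean on 5 of 5 arrays, and Stfa1 at -0.50 with 8 arrays at the signal limit. Single control arrays weigh on these values, as controls ranged from 6.78 to 10.38 for Clec4e, 7.11 to 9.97 for Csf3r and 7.05 to 10.37 for Hdc. Control replicate 4 was the highest for Clec4e and Csf3r. Control replicate 1 lay below every miR-132 array for Clec4e and Hdc. Macrophage and monocyte markers had a mean of -0.05 ± 0.27 and a median of 0.02 (adjusted p of 0.975), 8 lower and 9 higher, and the mean turned to 0.09 after quantile normalization. In that list Cd14 stood at -0.85 and Itgam at -0.59, the complement genes C1qa at 0.34 and C1qc at 0.30. Single arrays weigh on the first of these. Itgam was 11.95 on control replicate 4 and 9.74 to 10.37 on the other controls. Cd14 was 10.52 on miR-132 replicate 5 and 7.55 to 8.57 on the other miR-132 arrays. T and NK cell markers averaged 0.06 ± 0.10 (adjusted p of 0.729), 5 of 7 higher, with Cd2 at 0.16, Cd4 at 0.13, Cd3e at 0.11 and Cd3g at -0.13. Mast cell markers averaged 0.12 ± 0.20 (adjusted p of 0.729), 7 of 9 higher, with Cpa3 at 0.45, Cma1 at 0.35, Ms4a2 at 0.13 and Gata2 at 0.09. When single arrays were left out, neutrophil markers ranged from -0.74 (without control replicate 1) to -0.24 (without control replicate 4), macrophage markers from -0.19 (without miR-132 replicate 4) to 0.06 (without control replicate 1), T and NK cell markers from -0.00729 (without control replicate 2) to 0.11 (without control replicate 5) and mast cell markers from 0.00578 (without miR-132 replicate 4) to 0.23 (without control replicate 5).

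All 16 measured genes of hypoxia and glycolysis averaged lower, and 4 had an unadjusted p under 0.05. Hk2 measured 9.77 ± 0.68 in controls and 8.60 ± 0.59 with miR-132 (SD, n = 5 each). Slc2a1, a glucose transporter gene, differed by -1.45, the pyruvate kinase gene Pkm by -0.56 and the hypoxia-induced Ankrd37 by -0.41. The list averaged -0.56 ± 0.27 (SE, fry's p of 0.0529, adjusted p of 0.321). Here too miR-132 replicate 3 (10.77) lay near the top of the control range of 10.15 to 10.78, and without it the list passed (-0.78, adjusted p of 0.0198). With quantile normalization as well it did not pass (adjusted p of 0.262), as the difference went from -0.78 ± 0.16 to -0.62 ± 0.21 (SE, n = 4 and 5). Matrix proteases and their inhibitors averaged -0.42 ± 0.22 (adjusted p of 0.592), 13 of 17 lower, with Mmp9, Plaur at -0.91, Adam8 at -0.69 and Plau at -0.65. The last of these encodes urokinase and Plaur its receptor. Ligands of the epidermal growth factor receptor family averaged -0.45 ± 0.19 (adjusted p of 0.486), 5 of 6 lower, with Hbegf, Tgfa at -0.90, Nrg1 at -0.39 and Btc at 0.14. The exact permutation p of that list was 0.0317 (adjusted p of 0.413). Hippo pathway targets averaged -0.16 ± 0.12 (adjusted p of 0.619), 11 of 14 lower, with Ankrd1 at -0.99, Nuak2 at -0.41, Ajuba at -0.39 and, in the other direction, Ccn2 at 0.32. When single arrays were left out, Hippo targets ranged from -0.25 (without control replicate 4) to -0.09 (without control replicate 5).

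**Figure D2:**
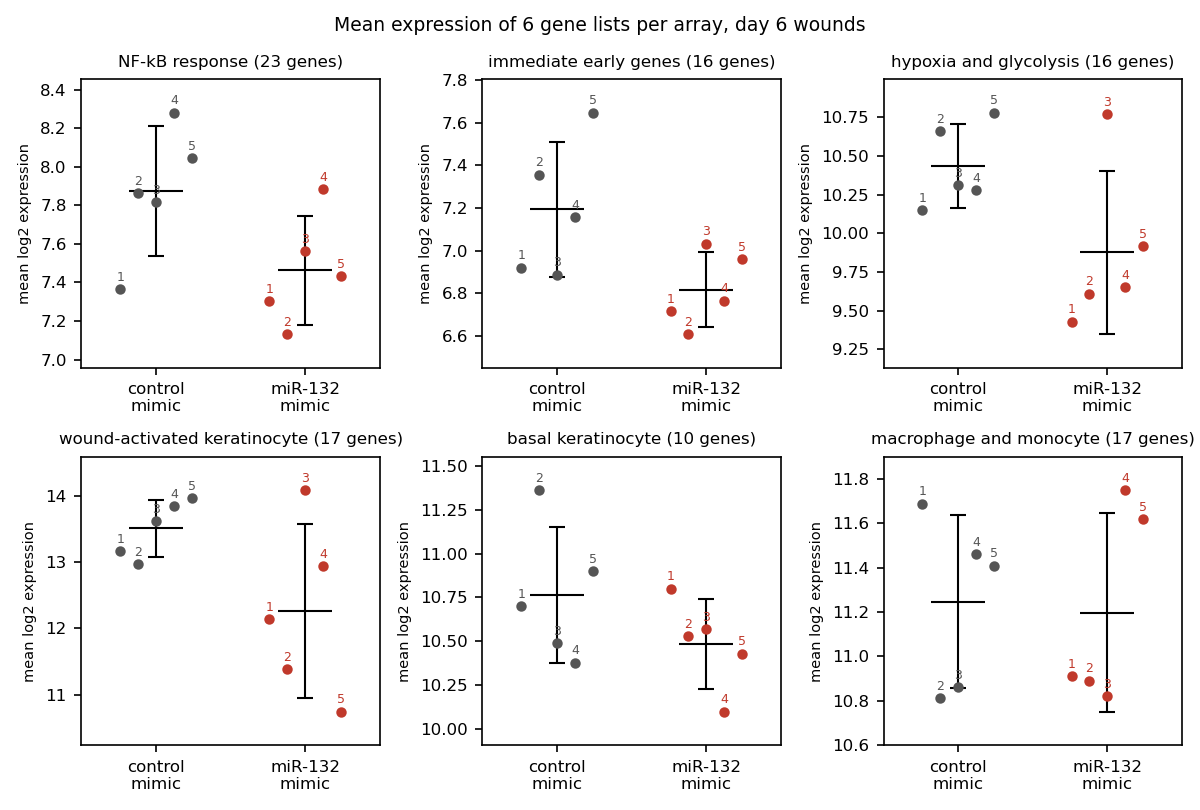
Mean log2 expression of the measured genes of 6 lists on each array (points, numbered by replicate), with the group mean (horizontal line) and SD (bars). In the wound-activated keratinocyte list miR-132 replicate 3 stands at 14.09, above every control array, and the other miR-132 arrays lie between 10.74 and 12.94.

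Among structural and stromal genes, collagen, fibroblast and endothelial lists averaged within 0.12 of the control mean, adipocyte markers higher, and muscle and sebaceous markers lower except with the hybridisation controls as a covariate, with wide spread and none past adjustment. Collagens and matrix genes averaged -0.11 ± 0.24 (SE, adjusted p of 0.802), 14 of 18 lower, with Col3a1 at -0.28, Col1a2 at -0.25, Fmod at -0.20 and Sparc at -0.15, and the list turned to 0.01 after quantile normalization. Fibroblast markers had a mean of 0.01 ± 0.22 and a median of -0.10 (adjusted p of 0.975), 6 lower and 5 higher, with Thy1 at 0.32, Fap at 0.22, Dcn at 0.05 and Fbln1 at -0.13. With the hybridisation controls as a covariate the mean was -0.02. Dcn read 17.88 on every control array and Sparc 16.99 on all controls but replicate 4. These bright clusters were nearly flat, so small differences there are uncertain. Endothelial markers averaged -0.10 ± 0.18 (adjusted p of 0.729), 10 of 13 lower, with Pecam1 and Plvap at -0.27, Flt1 at -0.25 and Vwf at -0.15. Adipocyte markers averaged higher for all 14 members, by 0.47 ± 0.59 (adjusted p of 0.729) and by 1.37 with the hybridisation controls as a covariate, with the adipokine genes Retn at 1.77 ± 1.24, Lep at 1.18 ± 1.16 and Adipoq at 0.84 ± 0.80, and the fatty acid transporter gene Cd36 at 0.47. Skeletal muscle genes averaged -0.39 ± 0.76 (adjusted p of 0.802), 15 of 18 lower, with Myh2 at -0.97, Myh4 at -0.86, Tnnt3 at -0.73 and Actn3 at -0.71. Sebaceous gland markers averaged -0.41 ± 0.43 (adjusted p of 0.729), 8 of 9 lower, with Elovl4 at -0.90, Fa2h at -0.88, Far2 at -0.68 and Elovl3 at -0.67. The muscle and sebaceous lists turned to 0.39 and 0.34 with the hybridisation controls as a covariate, which is partly confounded with treatment. When single arrays were left out, adipocyte markers ranged from 0.07 (without miR-132 replicate 1) to 0.79 (without control replicate 5), muscle genes from -0.86 (without miR-132 replicate 2) to -0.00481 (without miR-132 replicate 4), sebaceous markers from -0.71 (without miR-132 replicate 1) to -0.21 (without miR-132 replicate 3), collagens from -0.27 (without miR-132 replicate 5) to 0.03 (without miR-132 replicate 2), fibroblast markers from -0.10 (without miR-132 replicate 4) to 0.14 (without miR-132 replicate 3) and endothelial markers from -0.21 (without miR-132 replicate 5) to 0.03 (without miR-132 replicate 3). Without miR-132 replicate 1, Retn stood at 0.70, Lep at 0.41 and Adipoq at 0.23.

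Hair follicle markers averaged -0.04 ± 0.23 with a median of 0 (adjusted p of 0.880), 5 lower and 5 higher, and turned to 0.01 after median centring. Tchh stood at -0.49, Foxn1 at -0.33, Sox21 at 0.14 and Dlx3 at -0.12. Schwann cell and melanocyte markers averaged -0.06 ± 0.07 (adjusted p of 0.619), 5 of 6 lower, with Mitf at -0.13, Tyrp1 at -0.06, Mbp at -0.05 and S100b at 0.05, the last of these at -0.01 after quantile normalization. Cell cycle genes averaged 0.03 ± 0.19 (adjusted p of 0.975), 13 lower and 15 higher of 28, with Cenpe at 0.28, Ttk at 0.22, Cdk1 at 0.20 and Cdc20 at -0.23, and that list turned to -0.06 with the hybridisation controls as a covariate. Circadian clock genes averaged -0.05 ± 0.05 (adjusted p of 0.619), 11 of 16 lower, with Arntl at -0.40, Cry1 at -0.23, Cry2 at -0.10 and Ciart at -0.08. When single arrays were left out, hair follicle markers ranged from -0.18 (without miR-132 replicate 5) to 0.12 (without control replicate 5), Schwann cell and melanocyte markers from -0.09 (without miR-132 replicate 5) to -0.00817 (without miR-132 replicate 3), cell cycle genes from -0.07 (without control replicate 2) to 0.16 (without control replicate 4) and clock genes from -0.09 (without miR-132 replicate 1) to -0.03 (without control replicate 2).

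Over the 28 lists, fry gave 0 past an adjusted p of 0.05 and 2 at an unadjusted p under 0.05, a number that ranged from 0 to 5 when single arrays were left out. Fry for either direction, camera with an estimated correlation and the exact permutation test of list means also gave 0. The exact permutation p was 0.103 for the wound-activated, 0.0952 for the NF-kB and 0.0635 for the glycolysis list. It was 0.0476 for the immediate early and 0.238 for the basal keratinocyte list (adjusted p of 0.741 for the basal list and 0.413 for each of the others). Each exceeded fry's p for that list, whereas for the target and growth factor ligand lists it was below fry's p. Camera with a preset correlation of 0.01 gave 7, the wound-activated keratinocyte, NF-kB, hypoxia and glycolysis, immediate early and basal keratinocyte lists as lower and the interferon and adipocyte lists as higher. With an estimated correlation the adjusted p was 0.701 for each of the 5 lower lists and 0.778 for both higher ones. With the hybridisation controls as a covariate 0 lists passed, and besides the chemokine and adipocyte lists the mean grew by over 1.5 times for hypoxia and glycolysis (-1.05), immediate early (-0.57), collagen (-0.32), hair follicle (-0.23), macrophage (-0.18), interferon (0.31), T and NK cell (0.27) and mast cell genes (0.19), while it shrank as much for clock (-0.01) and endothelial genes (-0.04). After quantile normalization it shrank by over 1.5 times for basal (-0.17) and differentiated keratinocyte (-0.16), toll-like and NOD-like receptor (-0.05), Hippo (-0.07), target (-0.19), muscle (-0.22), endothelial (-0.02), Schwann cell and melanocyte (-0.03), clock (-0.02) and T and NK cell genes (0.02), and grew as much for alternative activation (0.28), cell cycle (0.11) and fibroblast genes (0.12). Without miR-132 replicates 2 and 5 it shrank as much for wound-activated (-0.46) and differentiated keratinocyte (-0.11), sebaceous (-0.13) and clock genes (-0.02), and grew as much for muscle (-0.67), endothelial (-0.22), hair follicle (-0.21), Schwann cell and melanocyte (-0.14), macrophage (-0.09), mast cell (0.24), cell cycle (0.13) and fibroblast genes (0.08). The difference depended on expression level across genes, which are not independent replicates. The median difference was 0.07 in the dimmest of 20 level bins, -0.14 in the bin around 12.15 and -0.03 in the brightest bin, around 17.3.

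**Figure D3:**
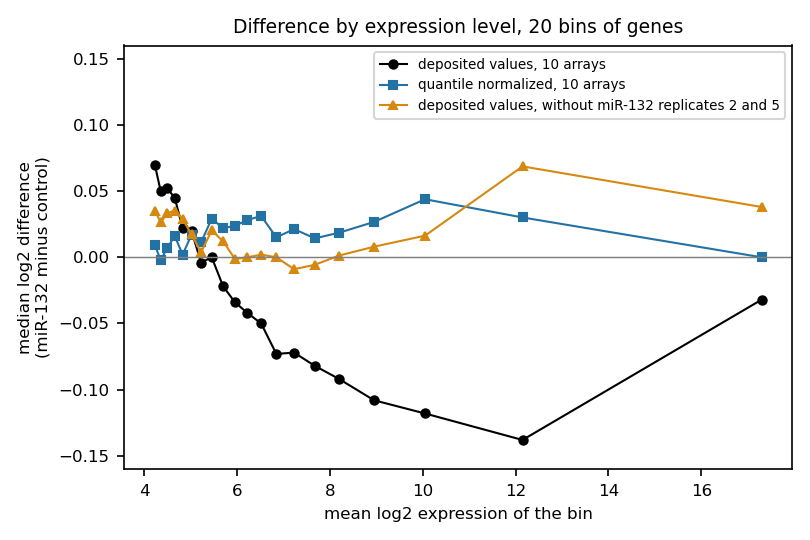
Median log2 difference (miR-132 minus control, vertical axis) in 20 bins of genes by mean log2 expression (horizontal axis), for the deposited values, after quantile normalization, and without miR-132 replicates 2 and 5. The deposited values run from 0.07 in the dimmest bin to -0.14 near a level of 12.15 and back to -0.03 in the brightest bin. The other lines stay between -0.01 and 0.07.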

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

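Among the tests in this part, leaving out miR-132 replicates 2 and 5, the tests of epidermis and leukocyte content, of epidermis in miR-132 replicate 3, and the splits for counts past adjustment were chosen after their results were seen. Arrays apart from their group were looked for in 334 groups of 5 values, of which chance marks about 1 in 20, or 16.7, and 22 were found.

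In 6 genes miR-132 replicate 3 stood above the other miR-132 arrays and close to or above the control mean: Zswim4 at 7.58 (others 6.58 to 6.76), Tgfa at 7.88 (5.77 to 6.34), Foxn1 at 5.44 (4.49 to 4.62), Egr3 at 6.20 (5.45 to 5.52), Plau at 10.68 (9.70 to 9.83) and Cdkn1a at 11.90 (10.10 to 10.50). Other miR-132 arrays apart from their group were replicate 1 in Thnsl1 (4.19, others 4.39 to 4.46) and in the clock list mean (6.09, others 5.87 to 5.93). Replicate 2 stood apart in Ly96 (8.65, others 8.10 to 8.23) and Clk3 (7.89, others 8.10 to 8.18), and replicate 5 in Krt5 (18.97, others 19.90 to 19.93). Replicate 4 stood apart in Dcn (18.16, others 17.86 to 17.88), Ccl8 (17.04, others 15.35 to 15.54) and Irak3 (8.95, others 7.97 to 8.24). Dcn read 17.88 on every control array, so its signal was nearly flat and the reading of replicate 4 is uncertain. Among controls, replicate 1 stood apart in Nrg1 (5.92, others 6.58 to 6.70) and in the interferon list mean (5.92, others 5.37 to 5.51). Control replicate 3 did so in Coprs (5.91, others 5.60 to 5.66) and Mitf (6.53, others 6.67 to 6.72). Control replicate 4 did so in Sparc (16.89, others all 16.99) and Itgam (11.95, others 9.74 to 10.37), and control replicate 5 in Ly96 (8.17, others 7.13 to 7.43) and Adipoq (8.22, others 5.20 to 5.98). The hybridisation controls, which the comparisons of genes use only as a covariate in 1 alternative, averaged 0.26 higher with miR-132 (exact permutation p of 0.0317, adjusted p of 0.254).

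Bright genes were lower and dim genes higher with miR-132, though the brightest of 20 level bins, around 17.3, had a median difference of only -0.03. The Spearman correlation across genes between level and difference was -0.32. It was -0.0207 without miR-132 replicates 2 and 5, the arrays with the narrowest signal range, so the trend was not seen without these 2 arrays. Quantile normalization took it to 0.0136, but gives all arrays the same distribution and so removes such a trend whatever its cause. Background control feature GC09 read 3.77 and 3.59 on replicates 2 and 5, and 3.23 to 3.40 on the other arrays. GC11 read 3.36 and 3.16, against 2.92 to 3.04. GC24 went the other way, at 3.49 and 3.55 with controls at 3.56 to 3.59. The labelling spike-in dap was lowest on replicate 2 (9.03) but read 10.05 on replicate 5, with controls at 9.17 to 9.87. These features were not tested against the range. Whether the narrow range came from the measurement or from the tissue therefore stays open.

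The NF-kB, immediate early, glycolysis and wound-activated keratinocyte lists were lower together. After quantile normalization each kept at least 77.3% of its mean difference, which argues against the signal distribution as the whole cause, although the wound-activated list stood at -0.46 without replicates 2 and 5. Less epidermis in the miR-132 biopsies could not be told apart from a lower wound response, since basal markers under the signal limit differed by -0.321 ± 0.26 (SE) and wound-activated ones by -1.34 ± 0.66. Fewer leukocytes stayed open too, with macrophage markers at -0.0474 and a wide error, neutrophil markers at -0.45, and the NF-kB list at -0.41. An effect of the mimic stays open, and so does chance, since 48 of 100 splits of the 10 arrays gave as many lists (2) at an unadjusted p under 0.05, with 9 as the highest of the other splits.

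In the NF-kB list miR-132 replicate 4 (7.88) was the highest miR-132 array, with replicate 3 at 7.56 and a control mean of 7.87. In the wound-activated, glycolysis and immediate early lists miR-132 replicate 3 was the highest, within or above the control range. Without it 55 genes passed adjustment. More epidermis in that biopsy stays open: its basal markers averaged only 0.0916 above the other miR-132 arrays where its wound-activated genes were 2.44 above, but they went both ways (Trp63 1.04, Itgb4 0.83 and Itga3 0.42 above, Dst at -0.86 and Krt15 at -2.40). On the axis from controls (0) to the other miR-132 arrays (1) over all genes replicate 3 stood at -0.212. This lay beyond the control range of 0.0438 to 0.462 on the side away from miR-132. The axis did not separate the groups, since miR-132 replicates 2 (0.448) and 4 (0.295) lay within the control range. The position therefore cannot decide whether replicate 3 was a control wound under a wrong label, which could not be excluded. Whether that wound took up little mimic was not tested. On the deposited values only 1 of 100 splits of the 9 remaining arrays, the real one, gave 55 genes (highest other 1). This array was singled out after its values were seen. With quantile normalization, the only other scaling run without that array, 0 genes passed on these 9 arrays. Among the 55 the lowest of limma's adjusted p was then 0.0610, close to the threshold. The count of 55 thus did not hold under that scaling. When 9 other splits of the 10 arrays were each given their most favourable omission, 0 reached 55 (highest 2), too few splits for a share under 0.05.

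With all 10 arrays chance could not be excluded for the count of genes. The 1419 genes at an unadjusted p under 0.05 were matched or exceeded in 15 of 100 splits, the real one included (highest other 2672). Each of the 5 splits that exchange only miR-132 replicate 3 for a control array gave more than 1419 (1453 to 2672, the highest with control replicate 2). These 5 do not point away from the treatment while the label and the delivery of that array stay open. Splits that kept replicate 3 in its group exceeded 1419 too. Exchanging miR-132 replicates 2 and 5 for control replicates 1 and 3 gave 1622. Exchanging miR-132 replicates 1 and 4 for control replicates 2 and 3 gave 1571. Replicate 3 therefore does not account for all such splits. The 0 genes and 0 lists past adjustment test nothing here, since all 100 splits have at least 0 (highest other 0 genes and 2 lists).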

How the results depend on the processing

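The alternatives without miR-132 replicates 2 and 5, with the hybridisation controls as a covariate, and with quantile normalization without miR-132 replicate 3 were chosen after seeing the data. The covariate is partly confounded with treatment, so changes under it cannot be assigned to either. Of 2911 values of 134 named genes under the alternatives, 2893 kept the sign they had with all arrays, as did 681 of 725 values of the 28 lists. Where a cause is not given below, the cause was not tested. The number of arrays and, for dim genes and those at the upper limit, the signal itself limit what could be seen.

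Leaving out single arrays, 0 to 55 genes passed adjustment, 944 to 2473 had an unadjusted p under 0.05, 0 to 2 lists passed and 0 to 5 lists had an unadjusted p under 0.05. The values 55, 2473 and 2 came without miR-132 replicate 3, and 944 came without control replicate 5. Every other setting run gave 0 genes past adjustment with limma. The count at an unadjusted p under 0.05 (1419) was 2617 with no level filter and 931 above the 75th percentile, from the number of genes tested, and 2642 with quantile normalization without replicate 3. Lists past adjustment numbered 7 by camera with the preset correlation, which assumes near-independent genes, and 0 with an estimated correlation (adjusted p of 0.701 to 0.778 for these 7). They numbered 1 with quantile normalization without replicate 3, where the wound-activated keratinocyte list passed (-1.56, adjusted p of 0.0309) and the hypoxia and glycolysis list did not (-0.62, adjusted p of 0.262). Lists at an unadjusted p under 0.05 (2) numbered 4 above the 75th percentile, 1 with the mean of features, 1 with median centring, 1 with quantile normalization, 4 with the covariate and 4 with quantile normalization without replicate 3.

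The labels do not say that replicate numbers pair the arrays, and the values could not settle it. Same-number correlations of deviations were 0.165, 0.140, 0.0431, -0.000447 and -0.0302. Replicates 3 to 5 correlated better with another number, while replicates 1 (0.165 against 0.164) and 2 (0.140 against 0.0891) did not. With the number as a block, 0 genes and 0 lists passed, 1264 genes and 1 list had an unadjusted p under 0.05.

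Signs turned in both small and larger differences. With no level filter the Schwann cell and melanocyte list was 0.019, and with median centring the hair follicle list 0.0058. Quantile normalization gave collagens 0.00956, chemokines 0.028, macrophages 0.0907 and S100b -0.0143. Array weights gave collagens 0.0143, chemokines 0.0657 and macrophages 0.0784. The covariate gave alternative macrophage activation -0.111, cell cycle -0.0638, fibroblasts -0.0216, Schwann cells and melanocytes 0.00535, sebaceous gland 0.339, muscle 0.388, Krt5 0.00768, Tyrp1 0.0899, Fa2h 0.314, Elovl3 0.522, Far2 0.810, Myh2 0.0190, Tnnt3 0.113 and Cd3g 0.0782. Quantile normalization without replicate 3 gave clock 0.0111, collagens 0.176, endothelium 0.129, chemokines 0.102, macrophages 0.218, Schwann cells and melanocytes 0.0222, Sparc 0.0895, Col1a2 0.0463, Col3a1 0.0553 and Pecam1 0.0371.

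Leaving out single arrays, differences ranged from -0.102 to 0.144 for fibroblasts, -0.184 to 0.115 for hair follicle, -0.20 to 0.0702 for chemokines, -0.0134 to 0.220 for interferon, -0.185 to 0.0633 for macrophages and -0.272 to 0.0290 for collagens. They ranged from -0.209 to 0.0335 for endothelium, -0.0657 to 0.157 for cell cycle, -0.00729 to 0.106 for T and NK cells, -0.0775 to 0.275 for Btc, -0.0190 to 0.111 for S100b, -0.0075 to 0.0675 for Dcn and -0.0985 to 0.003 for Mbp. The lists of hypoxia and glycolysis (-0.783 to -0.448) and of wound-activated keratinocytes (-1.72 to -0.879) kept their sign.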

Other observations

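The genes and tests of this part were chosen after their values were seen, except the random lists for the miR-132 targets on the deposited values. Outside the lists, several genes averaged more than 2-fold lower with miR-132, each at an unadjusted p under 0.05 and none past adjustment over all 10 arrays. Grhl3, a transcription factor needed for the skin barrier, differed by -2.06 ± 0.67 (SE, n = 5 per group), Cnfn, a cornified envelope gene, by -2.34 ± 0.97, Plet1, an epithelial surface protein gene, by -2.67 ± 0.73, and the late cornified envelope genes Lce3d and Lce3c by -2.04 ± 0.82 and -1.82 ± 0.72. Lypd3 differed by -2.12 ± 0.59 and the kallikrein gene Klk10 by -2.18 ± 0.94. Acod1, the itaconate-producing enzyme of activated macrophages, differed by -1.70 ± 0.70, and Cd44, a hyaluronan receptor, by -1.20 ± 0.37.

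Among the 55 genes that passed adjustment without miR-132 replicate 3, 6 of those that encode parts of cell junctions are described here. No list of junction genes was fixed or tested. There, with limma over 4 miR-132 and 5 control arrays, the desmosome genes differed by -1.68 for Pkp1 (adjusted p of 0.0355), -1.08 for Pkp3 (0.0395), -1.39 for Dsg3 (0.0411), -0.69 for Dsp (0.0463) and -1.48 for Jup (0.0488). Cdh1, which encodes E-cadherin, differed by -1.82 (0.0411). With all 10 arrays the differences were -1.19, -0.82, -1.10, -0.53, -1.02 and -1.45 for Pkp1, Pkp3, Dsg3, Dsp, Jup and Cdh1, none past adjustment. After quantile normalization without that array 0 of the 55 genes passed, although the differences of these 6 kept their sign. Pkp1 went from -1.68 ± 0.20 to -1.46 ± 0.28 (SE, adjusted p of 0.108), Pkp3 from -1.08 ± 0.15 to -0.97 ± 0.15 (0.0613), Dsg3 from -1.39 ± 0.20 to -1.16 ± 0.18 (0.062), Cdh1 from -1.82 ± 0.26 to -1.60 ± 0.29 (0.0955), Jup from -1.48 ± 0.23 to -1.24 ± 0.31 (0.161) and Dsp from -0.69 ± 0.10 to -0.62 ± 0.19 (0.203). Less epidermis in the miR-132 biopsies, left open above, could also lower these genes and the cornified envelope genes above. It was not tested for them. Of the 55 genes, 5 belonged to a list fixed beforehand, namely Egln3, Egr3, Gjb6, Cdkn1a and Foxn1. The connexin gene Gjb6 (-1.52) and Nectin1 (-1.45), also among the 55, encode junction proteins too.

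A hypothesis was that reported miR-132 targets were lower than expressed genes of like level in general, as a direct effect of the mimic would give. Their mean difference of -0.28 lay at the 0.39 percentile of 10000 random lists of the same size and level, whose central 95% ran from -0.22 to 0.03. After quantile normalization the mean was -0.19 (fry's p of 0.573), at the 0.43 percentile. As far as the choice of genes goes, this argues against general lowering as the whole cause of the list mean. That mean weighs the large differences of Hbegf (-1.44) and Mmp9 (-1.34), while the list median was -0.125. Random lists were not compared without these genes, so whether the other targets were lower than genes of like level stays open. The low percentile is not particular to targets. The NF-kB, immediate early and wound-activated lists lay at the 0 percentile and the glycolysis list at 0.01. The percentile also leaves open an indirect route, since Hbegf and Mmp9 also stand in the wound-activated keratinocyte and protease lists. Those lists were lower too. Random lists also ignore that genes of a list vary together between animals, so this percentile is no test across mice.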
